A study of Mus musculus with 28 samples.

How the data were processed

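The study profiled histone H3 trimethylated at lysine 9 (H3K9me3), a mark of silenced chromatin, and histone H3 acetylated at lysine 9 (H3K9Ac, spelled as in the labels), a mark of active promoters, by chromatin immunoprecipitation from micrococcal-nuclease-digested chromatin and sequencing. Per the labels, the cells were the mouse melanoma line B16OVA (called B16 here) and the mouse colon adenocarcinoma line MC38. Each line carried either an empty CRISPR vector (control) or a guide against Setdb1 (Setdb1 KO), the gene of an H3K9 methyltransferase. Each of the 4 groups of line and genotype had 3 numbered replicates per mark, which gave 24 libraries, and 4 input samples had no file to use. Nothing in the labels says that the replicates were separate cultures, so the p-values measure the spread between these samples.

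Per the submitters' processing notes, reads were trimmed with cutadapt (version not given), aligned to the mouse build mm10 with Bowtie2 2.1.0, handled with SAMtools 0.1.8, searched for enriched islands with SICER 1.1 and processed with deepTools 3.1.1. The deposited unit is a read count: per the labels and from the values, each file lists the islands of 1 library with the number of its own reads in each island, with no scaling between libraries. An island is a stretch of 200 bp bins enriched for reads. Which input served as background and how reads were filtered were not given in the sources used here. A region without an island has no entry, so a value of 0 stands for "no island called" and not for a measured absence of reads. For this reason no fold change is given where all 3 libraries of a group had no island, and the level of the other group is given instead.

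Island reads were apportioned by overlap to fixed 5 kb windows and to gene regions on chromosomes 1 to 19 and X, and rounded. Gene positions came from a RefSeq table of the GRCm38.p6 assembly (49554 genes), the assembly of mm10. The H3K9me3 region of a gene ran from its start to its end plus 2 kb on both sides. The H3K9Ac region had been planned as 2 kb around the 5' end. The gene table gave no strand, so the region was 2 kb on both sides of the gene end with more H3K9Ac island reads over the 12 libraries of the mark. Gene body regions were tried beside it, a choice made after the data were seen. Genes that overlap, and families of near-identical genes such as receptors and zinc finger genes, share reads that these files do not separate. RPM values are island reads per 1000000 counted reads of a library, after TMM scaling. The counted reads are those in the gene regions, or in the windows, that entered the edgeR fit. RPM values of genes and of windows are thus on different scales. Values are means ± SD over the n = 3 libraries of a group unless stated otherwise.

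Counts were compared with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, trended dispersion) in 1 fit per mark with all 12 libraries and a term per group. Regions needed a mean of at least 10 island reads over those libraries, and calls needed a Benjamini-Hochberg adjusted p under 0.05. Adjusted p-values in the text are edgeR's unless another tool is named. The contrasts were KO against control in each line, the difference of the KO effects between the lines (interaction), and MC38 control against B16 control. Covered length and mean reads per kb were compared with exact two-sided permutation tests, whose smallest possible p for 3 against 3 libraries is 0.1. Windows with at least 500 bp under islands in all 3 libraries of 1 genotype and none in all 3 of the other were counted and are called lost or gained. The overlap of H3K9me3 and H3K9Ac changes was tested with Fisher's exact test. Regions with island reads in all 6 libraries of a line were also tested with limma 3.58.1 on log2 of TMM-scaled RPM plus 0.5.

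Gene lists were tested with limma's camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the 15 lists of a comparison. The lists were antigen presentation by MHC class I, interferon and nucleic acid sensing, H3K9 methylation and heterochromatin factors, imprinted genes, germline genes, clustered protocadherins, zinc finger genes, olfactory receptors, vomeronasal receptors, melanocyte genes, gut epithelium genes, fibroblast and mesenchymal genes, leukocyte genes, housekeeping genes, and long-terminal-repeat restriction and retroviral receptors. The lists, tests, designs and alternatives were fixed before the data were examined, apart from the additions named below. Named genes were chosen by a rule fixed then. For each mark and line, genes with an adjusted p under 0.05, a fitted log2 change of at least 1 in size and no overlap between the genotypes' libraries were taken, limited to protein-coding genes with an established symbol. The 6 with the smallest p in each direction were named. The rule added up to 3 members of each list by smallest p, whether or not they passed, then Setdb1, Actb and Gapdh, 12 lineage genes for the comparison of the lines, and the 3 windows with the smallest p in each direction at least 1 Mb apart. Genes named outside the rule are said to be so. A window picked by the rule is not reported here.

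Same-numbered control and KO libraries were checked for shared deviations from their group means across 5 kb windows. For H3K9Ac every pair correlated above 0.1 (0.203, 0.452 and 0.377 in B16, 0.105, 0.415 and 0.254 in MC38), so the numbers were treated as pairing these libraries and the fit with the replicate block is given where it changed a result. The H3K9me3 numbers did not pair the libraries by this measure.

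The alternatives were DESeq2's size factors in edgeR, total island reads as the only scaling, the DESeq2 1.42.0 Wald test, no filter, stricter islands (at or above their own library's median reads per kb), islands of at least 1 kb, 10 kb windows, other overlap minimums, only the 6 libraries of a line, the replicate block, and each replicate left out. TMM within each chromosome, the gene body region, and extra counts over zinc finger genes, over windows lost in both lines and over the islands of called genes in the other line were added after the data were seen. So were the counts by island presence of windows gained in both lines and of windows changed in both marks. The tests of library depth and of chromosome shares were outside the first plan too. Other splits of the libraries were refitted, all 10 splits of 3 against 3 and 25 for the interaction. The test code was checked on simulated counts with 200 changed genes. At a dispersion of 0.1, changes of 4 on the log2 scale were recovered in 100% of cases in every comparison. At the H3K9me3 data's own median dispersion of 4.56, 0% were recovered in B16 and in MC38, and at that of H3K9Ac (0.304) 60.6% were. Islands in primer binding sites of retroviral elements had been planned but were not analysed here, because they need a genome sequence. Islands on the Y chromosome and the mitochondrial genome were left out of all window and gene comparisons. Totals of island reads, covered lengths and reads per kb kept them, apart from the covered length of stricter islands. Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9) and R 4.3.3 (data.table, version 1.17.8) were used.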

Results

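H3K9me3 and H3K9Ac were mapped in B16 melanoma and MC38 colon adenocarcinoma cells with and without Setdb1, an H3K9 methyltransferase of silenced chromatin, in 3 libraries per line, genotype and mark. The series asked how these marks lie on loci where exons join transposable elements. The 12 H3K9me3 libraries held 15200766 to 45419584 island reads and the 12 H3K9Ac libraries 28453371 to 78087809. Around Setdb1 itself, H3K9Ac was 65.7 ± 5.7 RPM in B16 control and 70.1 ± 11.3 RPM in B16 KO libraries, and 56.5 ± 5.8 and 62.5 ± 6.2 RPM in MC38. A guide that damages the coding sequence need not change acetylation of the gene, so these values do not check the knockout. Actb and Gapdh, 2 genes active in all cells, had no H3K9me3 island in any library.

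More of the B16 genome lay under H3K9me3 islands in KO than in control libraries. The covered length was 312 ± 23.4 Mb in control and 401 ± 32.2 Mb in KO libraries, a difference of 89.4 Mb with every KO library above every control (exact permutation p = 0.1, the smallest possible). H3K9Ac islands in B16 covered 395 ± 24.3 Mb in control and 443 ± 5.79 Mb in KO libraries, again without overlap (exact permutation p = 0.1). Island reads per kb were alike for H3K9me3 in B16, at 58.3 ± 11.6 in control and 57.3 ± 6.16 in KO libraries (exact permutation p = 0.9). In MC38 they were 52.1 ± 3.83 in control and 77.0 ± 13.4 in KO libraries for H3K9me3, without overlap (exact permutation p = 0.1). H3K9Ac reads per kb had exact permutation p = 0.5 in B16 and 0.4 in MC38, in tests that leave out the pairing by number. In MC38 each KO library lay below the control of its number, at 109 and 102, 158 and 92.8, and 72.1 and 64.4 in control and KO. The B16 pairs went both ways. In MC38 the covered lengths overlapped, at 380 ± 62.0 and 407 ± 177 Mb for H3K9me3 (exact permutation p = 1) and 436 ± 36.3 and 441 ± 0.929 Mb for H3K9Ac (exact permutation p = 0.7). MC38 KO replicate 3 had 215 Mb and KO replicate 1 had 563 Mb of H3K9me3 islands. Without KO replicate 1 the MC38 H3K9me3 difference was -51.4 Mb and without KO replicate 3 it was 123 Mb, and without control replicate 1 the MC38 H3K9Ac difference was -14.2 Mb.

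**Figure D1:**
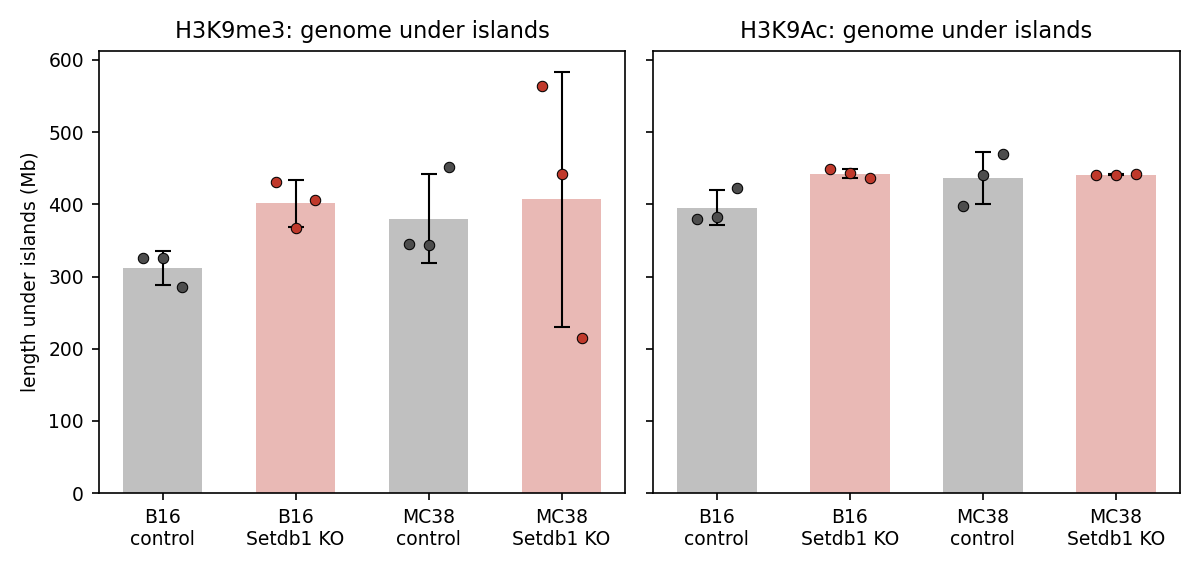
Length of the genome under islands (Mb, y axis) per library (points) with group means and SD (n = 3), for H3K9me3 and H3K9Ac in control and Setdb1 KO libraries of B16 and MC38. In B16 all KO libraries lie above all control libraries for both marks, and in MC38 the genotypes overlap.

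In B16, Setdb1 KO libraries had H3K9me3 islands over genes that were bare in control libraries and had none over others that were covered. H3K9me3 rose at Kprp and Lelp1, genes of the outer skin layer. They had no island in any of the 3 control libraries and 28.7 ± 17 and 24.4 ± 22.4 RPM in KO libraries (adjusted p = 0.0102 and 0.0122). It also rose at Reg3a, an antimicrobial lectin of the gut, from no island in any control library to 37.2 ± 11.4 RPM (adjusted p = 0.0111). The sperm tail gene Fscb reached 25.3 ± 13.4 RPM and BC051665 18.7 ± 6.74 RPM, both with no island in any control library (adjusted p = 0.0102 for each). At Phactr3, a regulator of protein phosphatase and actin, H3K9me3 rose from 35.8 ± 17.5 to 638 ± 196 RPM, a log2 change of 4.16 (SE 0.53, adjusted p = 0.0111). In MC38 these 6 genes carried H3K9me3 in all libraries of both genotypes, for example Phactr3 with 402 ± 88.3 and 485 ± 116 RPM.

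The opposite change was seen at Dclk1, a kinase related to doublecortin, where 41.8 ± 16 RPM in B16 control libraries contrasted with no island in any of the 3 KO libraries (adjusted p = 0.00623). H3K9me3 was likewise lost at the metalloprotease gene Adam12 (47.2 ± 9.86 RPM in control, adjusted p = 0.0102) and the aminopeptidase gene Aopep (50.2 ± 20.3 RPM, adjusted p = 0.0117). Mblac2 (31 ± 14.9 RPM in control, adjusted p = 0.0136), Nol4 (29.9 ± 3.83 RPM, adjusted p = 0.0136) and the transporter gene Abca8a (49 ± 14 RPM, adjusted p = 0.0156) lost it too. None of these had an island in any KO library. MC38 kept islands at these 6 genes in all libraries of both genotypes. Steady islands in the other line were nearly a condition of a call in this fit. Of 906 genes with islands in all 3 libraries of 1 B16 genotype and none of the other, 79 were called, and 78 of these had islands in all 6 MC38 libraries, against 2.66% of those not called. These 12 genes therefore do not show that the KO effect differed between the lines.

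Of 25677 gene regions measured, H3K9me3 rose at 42 and fell at 38 in B16, and of 269906 windows it rose in 795 and fell in 244. Of 8591 windows with island reads in all libraries of 1 B16 genotype and none of the other, 1037 were called, and 1035 of these had islands in all 6 MC38 libraries, so where the calls lay depended on MC38 as well. Nearly every called window was a contrast of island and no island, since 794 of the 795 higher windows had no control island and 243 of the 244 lower windows had no KO island. Chromosome 6 held 180 of the higher windows (22.6%), chromosome 8 held 124 (15.6%) and chromosome 13 held 93 (11.7%). The longest run of higher windows covered 40 kb inside Tmem132d on chromosome 5 (128185001 to 128225000), and the next with a gene covered 25 kb of Ptprn2 on chromosome 12 (117090001 to 117115000). Chromosome 3 held 100 of the lower windows, of 22530 tested there, and chromosome 13 held 53 of 11409. Of the lower windows with the smallest p, the one near Fabp5 on chromosome 3 (from 10000001) had 11.5 ± 1.70 RPM in control and no KO island. The calls rested on the fit with all 12 libraries, since edgeR on the 6 B16 libraries alone called 0 genes and 0 windows (1950 and 11577 at an unadjusted p under 0.05), while DESeq2 on all 12 libraries called 2253 genes and 27999 windows. The gene count was 165 without control replicate 1, 122 without KO replicate 2 and 52 without MC38 control replicate 3. Stricter islands left 100 higher and 92 lower windows and 5 higher and 17 lower genes. With 1 library left out, the gene split ran from 129 higher and 36 lower (without control replicate 1) to 45 and 64 (without control replicate 3). Of the 13 B16 genes named here for a call, Zfp382 included, 3 still passed with stricter islands, 1 with the replicate block and 0 with the 6 B16 libraries alone, while 13 passed with DESeq2.

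Zinc finger genes, many of which encode repressors of transposable elements, had lower H3K9me3 as a group in B16 KO libraries (camera adjusted p = 9.19e-11, adjusted p = 0.267 with an estimated correlation). Of 258 measured members, 108 (41.9%) had all 3 KO libraries below all 3 control libraries and 1 was above. The highest other split of the B16 libraries separated 20 members. Chance gives 10% for both directions together, and all measured genes had 9.44% below and 5.89% above. Summed over the list, H3K9me3 was 24505, 17705 and 17078 RPM after TMM scaling in the control libraries and 16532, 12964 and 14487 in the KO libraries (exact permutation p = 0.1). Of the 133 members with islands in all 6 libraries, 109 had a log2 change below 0, with a median of -0.54 where the median of all such genes was 0.00. A single member passed the test over all genes and the test adjusted over the list alone: Zfp382 had 63.7 ± 19.8 RPM in control and no island in any KO library (adjusted p = 0.0268). Its call was lost without any 1 of the 3 control libraries or KO replicate 3 (adjusted p up to 0.0886). Zfp65 went from 65.2 ± 15.8 to 10.3 ± 5.44 RPM and Zfp677 from 17.1 ± 2.16 to 0.211 ± 0.366 RPM without passing (adjusted p = 0.313 and 0.297). By limma on the members with islands in all 6 libraries, 53 were lower and 0 higher at an unadjusted p under 0.05, 7 were lower when adjusted over the list alone and 0 when adjusted over all genes. The direction was the same under TMM, DESeq2's size factors and total island reads, which moved the median of all genes from 0.01 to -0.21 and that of the list from -0.55 to -0.76.

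H3K9 methylation and heterochromatin factors, a list that holds Setdb1's own partners, were also lower in H3K9me3 in B16 KO libraries (camera adjusted p = 0.00274, adjusted p = 0.267 with an estimated correlation). None of the 12 measured members passed over all genes or adjusted over the list alone in edgeR. All KO libraries lay below all controls in 5 (10% by chance for both directions together, 1 member in the highest other split). By limma 4 of the 5 with islands in all 6 libraries were lower adjusted over the list alone. Atf7ip, a cofactor of Setdb1, had 102 ± 25.3 RPM in control and 16.5 ± 5.22 RPM in KO libraries (adjusted p = 0.64). Morc2a, which acts with the HUSH silencing complex, had 24.9 ± 3.02 RPM in control and no island in any KO library (adjusted p = 0.397). Clustered protocadherins, cell-surface adhesion genes of neurons, were called lower (camera adjusted p = 0.000191, adjusted p = 0.952 with an estimated correlation), with 10 of 43 members having all KO libraries below all controls. The highest other split separated 13 members, so the 10 are no sign of an effect of genotype. The sign was not uniform, since of the 14 members with islands in all 6 libraries only 1 lay below 0. Vomeronasal receptors were called higher (camera adjusted p = 0.0194, adjusted p = 0.952 with an estimated correlation) with 0 of 231 members passing, 13 above and 3 below without overlap. The highest other split separated 23 of these receptors. In receptors with islands in all 6 libraries the median was 0.12, and -0.10 with total island reads as the only scaling.

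The other lists were not called in B16 H3K9me3. Olfactory receptors had an adjusted p of 0.0621 with 0 of 1208 members passing. Olfr336-ps1 had 0.67 ± 0.845 RPM in control and 22.5 ± 4.6 RPM in KO libraries (adjusted p = 0.335). No member passed among 30 imprinted, 31 germline, 13 interferon and nucleic acid sensing and 6 antigen presentation genes. The same held for 12 melanocyte, 15 gut epithelium, 6 fibroblast and mesenchymal, 12 leukocyte and 2 housekeeping genes and 8 genes of long-terminal-repeat restriction. The adjusted p-values of these 10 lists ran from 0.214 to 0.936. Adjusted over the list alone, 1 gut epithelium gene was lower. The imprinted neighbours Meg3 and Rtl1 had 40.2 ± 20.9 and 22.1 ± 24.6 RPM in control and 192 ± 56.5 and 227 ± 58.3 RPM in KO libraries (adjusted p = 0.51 and 0.808). Zc3hav1, an antiviral protein that binds viral RNA, had 28.6 ± 12.3 RPM in control and no island in any KO library (adjusted p = 0.51).

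**Figure D2:**
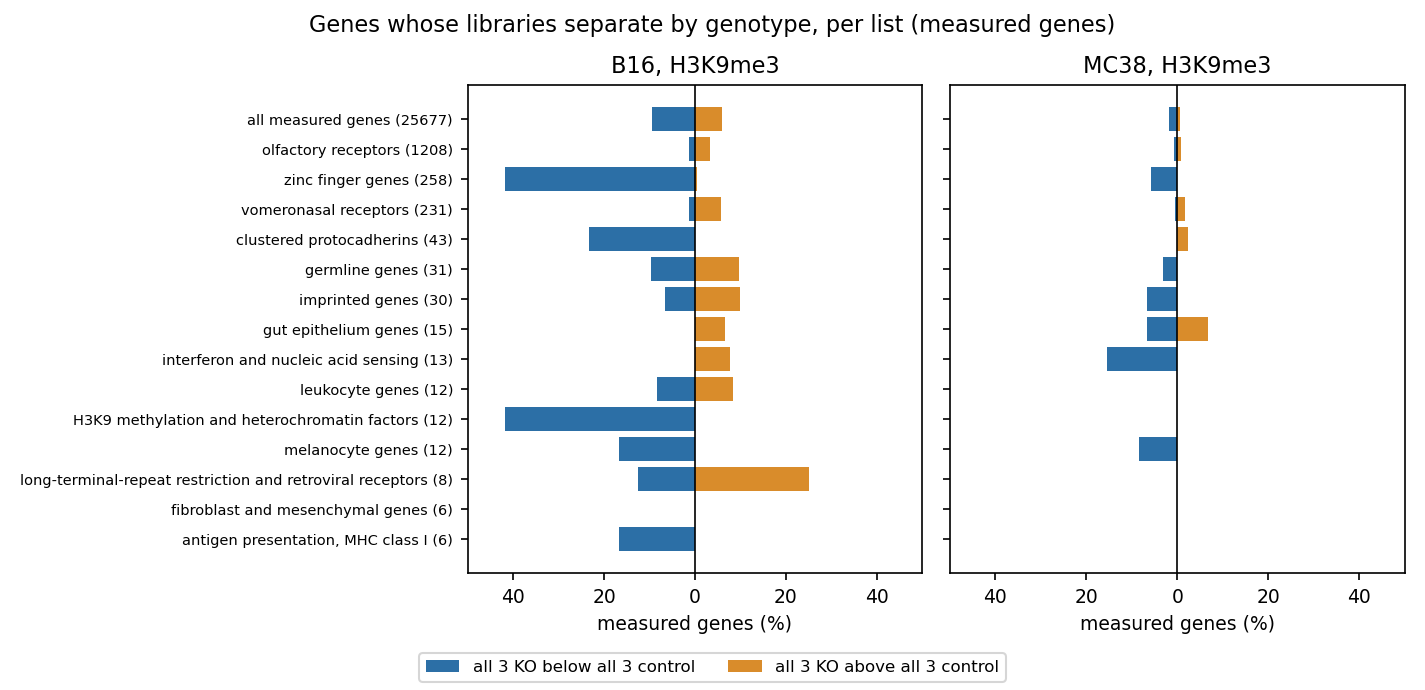
Share of measured genes (%, x axis) of each list, and of all measured genes, with all 3 KO libraries below (blue, left) or above (orange, right) all 3 control libraries in H3K9me3, for B16 and MC38; numbers of measured genes are in brackets and housekeeping genes (2 measured) are left out. In B16 41.9% of zinc finger genes lie to the left against 9.44% of all measured genes, and in MC38 5.81% against 1.73%.

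In MC38, edgeR with all 12 libraries called fewer regions in H3K9me3, most of them lower. H3K9me3 was lost at Oasl1, an interferon-induced regulator of antiviral signalling, which had 60.1 ± 18.5 RPM in control and no island in any of the 3 KO libraries (adjusted p = 0.00775). The same happened at Litaf, a gene induced by bacterial lipopolysaccharide (108 ± 23 RPM in control, adjusted p = 0.00775), and Klra4, a natural killer cell receptor of the Ly49 family (25.9 ± 3.7 RPM, adjusted p = 0.00775). It happened too at Serpinb1c (19.7 ± 3.19 RPM, adjusted p = 0.00934), the neuronal exchange factor gene Ngef (33.2 ± 18.6 RPM, adjusted p = 0.0104) and Il21r, the interleukin 21 receptor (21.6 ± 8.5 RPM, adjusted p = 0.0104). Islands appeared at the pheromone receptor gene Vmn2r56 (60.1 ± 43 RPM in KO, adjusted p = 0.0104) and the lectin gene Clec4g (35.6 ± 23.2 RPM, adjusted p = 0.0216), neither of which had an island in any control library. B16 had islands at these 8 genes in all libraries of both genotypes. That too came with the calls: of 173 genes with islands in all libraries of 1 MC38 genotype and none of the other, 35 were called, all with islands in all 6 B16 libraries, against 9.42% of those not called.

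H3K9me3 rose at 3 and fell at 32 gene regions in MC38, and it rose in 37 and fell in 111 windows, all of them with islands in 1 genotype alone. The split was 12 higher and 77 lower windows with DESeq2's size factors. It turned to 441 higher and 298 lower without MC38 KO replicate 3 and to 7816 and 7534 with DESeq2, and was 131 and 151 without MC38 control replicate 2. The longest run of lower windows covered 20 kb in Fam160a1 on chromosome 3 (85725001 to 85745000). The window with the smallest p lay near the start of chromosome 18 (3005001 to 3010000), with 33.6 ± 4.08 RPM in control and no KO island (adjusted p = 2.77e-06). A window at Icos, a T cell costimulator gene, had 8.73 ± 3.15 RPM in KO and no control island. Across all windows edgeR's interaction passed at 1157 (885 higher and 272 lower in B16 relative to MC38). These MC38 counts hung on single libraries: without any 1 of the 6 MC38 libraries 62 to 154 genes were called. Without B16 KO replicate 2 or 3 or control replicate 2 or 3 there were 12, 10, 12 and 19 genes. The fit by edgeR on the 6 MC38 libraries alone called 0 genes (200 at an unadjusted p under 0.05) while DESeq2 called 2010. Of the 9 MC38 genes named here for a call, Olfr223 included, 2 still passed with stricter islands and 0 with the replicate block or the 6 MC38 libraries alone, while 9 passed with DESeq2.

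Zinc finger genes were also called lower in MC38 H3K9me3 (camera adjusted p = 0.0169, adjusted p = 0.822 with an estimated correlation). Of 258 members, 15 had all KO libraries below all controls and 0 above, against 1.73% and 0.596% of all genes and a chance share of 10% for both directions together. The highest other split of the MC38 libraries separated 41 members, so this count does not set the genotypes apart. Of the 119 with islands in all 6 libraries, 100 lay below 0 (limma median -0.28, all genes -0.11). The summed signal did not separate beyond chance (exact permutation p = 0.2). No member passed over all genes, by edgeR or by limma. Zfp382 alone was lower in edgeR adjusted over the list alone, with 41.9 ± 16.4 RPM in control and no island in any KO library (adjusted p = 0.0582). The difference between the lines in this list was called (camera adjusted p = 0.000848, adjusted p = 0.917 with an estimated correlation). Vomeronasal receptors were called higher (camera adjusted p = 0.0169, adjusted p = 0.822 with an estimated correlation), with Vmn2r56 alone passing. Olfactory receptors were called higher too (camera adjusted p = 0.0452, adjusted p = 0.874 with an estimated correlation). The 1 member that passed, Olfr223, fell from 17.4 ± 11.3 RPM to no island in any KO library (adjusted p = 0.039). With the replicate block neither receptor list was called (camera adjusted p = 0.0531 for vomeronasal and 0.106 for olfactory receptors).

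The remaining lists were not called in MC38 H3K9me3, with adjusted p from 0.0775 for H3K9 methylation factors to 0.836. Among 13 interferon and nucleic acid sensing genes, Oasl1 passed and Mx1, an interferon-induced antiviral gene, did not, with 33.1 ± 15.4 RPM in control and no island in any KO library (adjusted p = 0.567). Zfp809, a repressor of retroviral sequences, had 22.6 ± 20.2 RPM in control and no island in any KO library (adjusted p = 0.431).

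Windows with islands in all 3 libraries of 1 genotype and none in the other were counted without a model. In B16, 4721 windows gained and 2726 lost H3K9me3 islands in KO libraries, and in MC38 353 gained and 680 lost them. For H3K9Ac, 1323 windows were gained and 178 lost in B16, and 474 gained and 330 lost in MC38. The windows lost from H3K9me3 in both lines numbered 22 in 18 regions, where independent losses among the 18803 windows that could be lost in both gave 6.53 (Fisher's exact test, odds ratio 3.73, p = 7.23e-07, windows not being independent). Of 400 pairs of splits 21 gave as many, so chance is not excluded by this count. Within the 18803, median control island density lay at the 30.2 percentile for the shared windows and the 40.1 percentile for windows lost in either line. The overlap was not adjusted for density. The 22 windows included Zfp382 (chromosome 7, 30135001 to 30145000), the calcium release protein gene Trdn (chromosome 10, 33185001 to 33195000), the sterol carrier gene Scp2 and the sialyltransferase gene St6galnac5. These genes were picked from the shared windows after their values were seen.

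At Zfp382 (chromosome 7, 30121833 to 30140758) the loss of H3K9me3 in B16 came with H3K9Ac inside the gene. The window from 30130001 had 7.76 ± 1.65 RPM of H3K9me3 in B16 control and no island in KO libraries, and it had 6.51 ± 0.382 RPM of H3K9Ac in KO and no island in control libraries. In MC38 the window from 30135001 had 10.2 ± 4.25 RPM of H3K9me3 in control and no island in KO libraries, and H3K9Ac from 30130001 reached 1.59 ± 2.75 RPM, from 1 KO library.

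**Figure D3:**
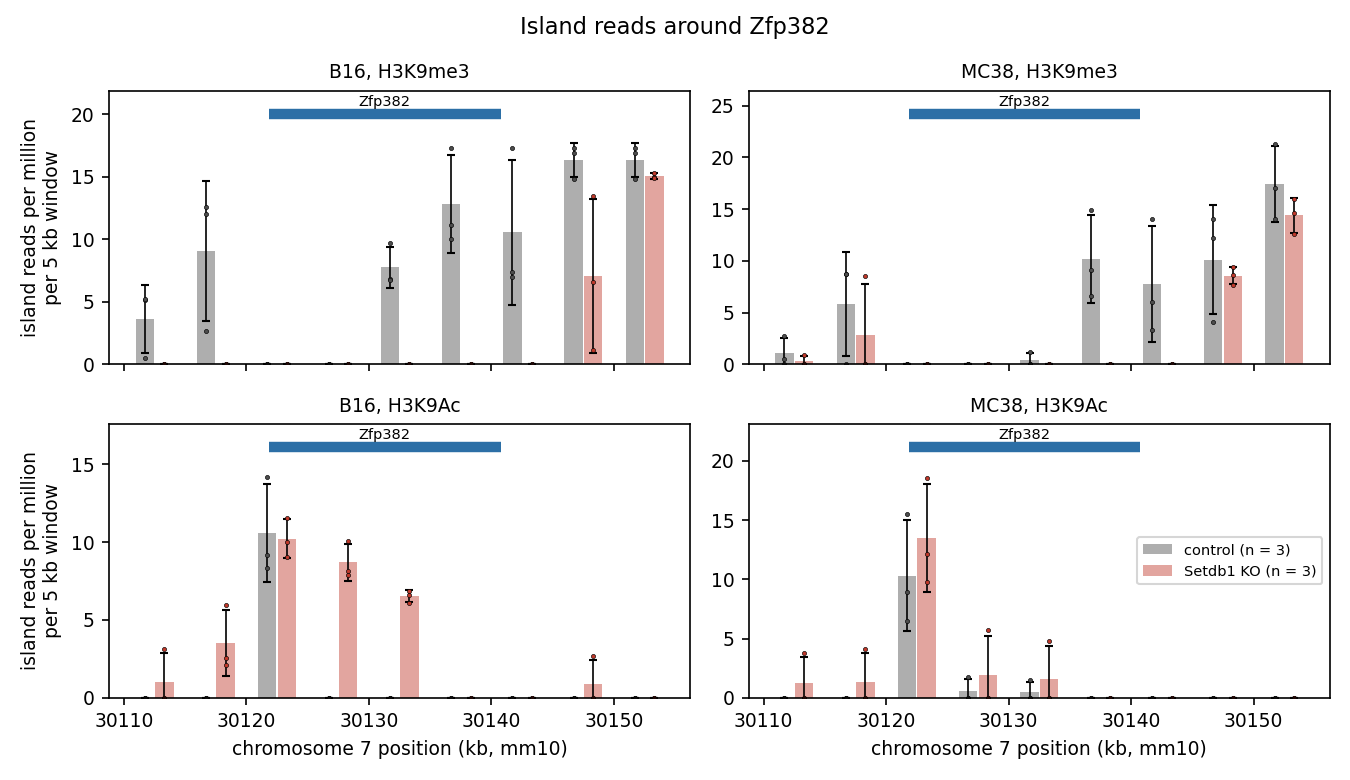
Island RPM per 5 kb window (y axis) along chromosome 7 around Zfp382 (x axis, kb, mm10), as means (bars), SD (lines) and libraries (points), n = 3 per genotype. H3K9me3 windows over the right part of the gene hold islands in control and none in KO libraries in both lines, and B16 KO libraries hold H3K9Ac islands where B16 control libraries hold none.

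H3K9Ac in B16 rose at H2-T24, a non-classical MHC class I gene, from no island in any of 3 control libraries to 32.2 ± 6.94 RPM in KO libraries (adjusted p = 6.7e-05). It also appeared at Faap20, a gene of the Fanconi anemia pathway (44.5 ± 5.04 RPM in KO, adjusted p = 0.000231) and the co-chaperone gene Dnajc18 (18.6 ± 6.82 RPM, adjusted p = 0.00194). Syna, the placental syncytin A gene derived from a retroviral envelope, reached 21.6 ± 17.7 RPM (adjusted p = 0.0118). None of these had an island in any control library within the 2 kb on both sides of the gene end used. Over gene bodies the log2 changes were 1.52 for H2-T24, 0.29 for Faap20, 0.42 for Dnajc18 and 0.26 for Syna. The zeros thus do not extend to the whole gene. MC38 had H3K9Ac at these 4 genes in both genotypes, as did all 21 genes called in B16 with islands in 1 genotype alone (4.72% of such genes not called). The kinesin gene Kif17 rose from 10.9 ± 1.86 to 36.1 ± 2.77 RPM (log2 1.73, SE 0.24, adjusted p = 0.0264). H3K9Ac fell at Kdm5a, an H3K4 demethylase, from 103 ± 12.5 to 46.6 ± 2.82 RPM (log2 -1.15, SE 0.15, adjusted p = 0.0229), and at its neighbour Ccdc77 which shares that gene end (log2 -1.19, adjusted p = 0.0241). It fell at the chloride transporter gene Clcn6 from 89.6 ± 10.6 to 43.8 ± 1.57 RPM (log2 -1.03, SE 0.15, adjusted p = 0.0374).

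Across the genome H3K9Ac rose at 21 and fell at 9 of 31664 gene regions in B16, and rose in 286 and fell in 36 of 201802 windows, 262 of the higher ones without a control island. The longest run of higher windows covered 15 kb of Nfatc3 on chromosome 8 (106065001 to 106080000), and a window in Sirt5, a mitochondrial deacylase gene, had 5.58 ± 0.372 RPM in KO and no control island. With the replicate number as a block, Kif17, Kdm5a, Ccdc77 and Clcn6 no longer passed (adjusted p = 0.0665, 0.0946, 0.102 and 0.149). Kif17, Kdm5a and Ccdc77 also lost the call without any 1 KO library (adjusted p up to 0.0839, 0.124 and 0.135). Clcn6 lost it without any 1 B16 library other than control replicate 3 (adjusted p up to 0.166). Over gene bodies, a region chosen after the data were seen, none of the 8 named genes passed by edgeR and the log2 change of Kdm5a was 0.16. With stricter islands 4 of the 8 passed, with the 6 B16 libraries alone 0 and with DESeq2 8. The gene count was 57, 70 and 74 without control replicates 1, 2 and 3 (32 higher and 38 lower without replicate 2), and 0 with the 6 B16 libraries alone, where 1168 genes had an unadjusted p under 0.05 and DESeq2 on all 12 libraries called 969.

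Of the lists, housekeeping genes were called lower in B16 H3K9Ac (camera adjusted p = 0.025, adjusted p = 0.964 with an estimated correlation) with 0 of 20 members passing in edgeR over all genes or adjusted over the list alone. A log2 change below 0 was seen in 17 of 20 under every scaling, and Tubb5, a tubulin gene, had 72.3 ± 11.2 and 56.5 ± 7.38 RPM (adjusted p = 0.897). The other 14 lists were not called (adjusted p from 0.572 to 0.984). Syna was the 1 passing member among 14 genes of long-terminal-repeat restriction and retroviral receptors. In edgeR no member passed among 366 zinc finger, 35 interferon and nucleic acid sensing, 21 antigen presentation, 32 imprinted and 31 germline genes and 30 H3K9 methylation factors. The same held for 49 protocadherins, 102 olfactory and 15 vomeronasal receptors, 20 melanocyte, 20 gut epithelium, 13 fibroblast and 13 leukocyte genes. Tap2, a peptide transporter of antigen presentation, had 24.9 ± 4.57 and 32.1 ± 1.62 RPM, and the pigment gene Tyr had 110 ± 9.4 and 100 ± 7.67 RPM (adjusted p = 1 for both).

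In MC38, H3K9Ac rose at Batf2, an interferon-induced transcription factor gene, from no island in any control library to 31 ± 1.98 RPM in KO libraries (adjusted p = 0.00581). It rose likewise at the acyl-CoA thioesterase gene Acot1 (11.9 ± 6.3 RPM in KO, adjusted p = 0.00581) and the sperm potassium channel gene Kcnu1 (15.1 ± 0.36 RPM, adjusted p = 0.0103). Akap7, an anchor of protein kinase A, and Thegl, a testis gene, had 14.7 ± 3.81 and 15.9 ± 3.86 RPM in control and no island in any KO library (adjusted p = 0.0106 and 0.0164). B16 had H3K9Ac at these 5 genes in both genotypes, as it did in all 6 libraries at each of the 22 genes called in MC38 (8.33% of genes with islands in 1 MC38 genotype alone that were not called). With the replicate block, Kcnu1 and Thegl no longer passed (adjusted p = 0.0504 and 0.0761), and over gene bodies none of the 5 passed. Their log2 changes over gene bodies were 2.54 for Batf2, 1.78 for Acot1, 2.05 for Kcnu1, -0.24 for Akap7 and -3.10 for Thegl. The missing islands thus concern the gene end used and not the whole gene. With stricter islands or the 6 MC38 libraries alone 0 of the 5 passed, and with DESeq2 5.

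H3K9Ac rose at 14 and fell at 8 gene regions in MC38, and rose in 101 and fell in 60 windows, 99 of the higher ones without a control island. A window inside Jazf1, a zinc finger gene of metabolism (chromosome 6, from 52855001), had 6.11 ± 0.760 RPM in KO and no control island, and another in the same gene (from 52815001) had 6.05 ± 1.71 RPM in control and no KO island. The replicate block gave 12 genes and 75 windows in place of 22 and 161. The gene count was 44 to 102 without 1 of the 6 MC38 libraries and 14 without B16 KO replicate 1. Lower regions outnumbered higher ones without MC38 KO replicate 1 (27 higher and 45 lower genes, 152 and 193 windows), and in windows without KO replicate 3 (302 and 320). The interaction passed at 431 H3K9Ac windows, 268 with the replicate block. No list was called in MC38 H3K9Ac (lowest adjusted p 0.302, for clustered protocadherins and olfactory receptors) and none of the members passed over all genes by edgeR. Adjusted over the list alone, the interferon gene Mx1 was higher, with no island in any control library and 13.7 ± 13 RPM in KO libraries, from 2 of them. H2-D1, a classical MHC class I gene, had 43.8 ± 6.38 and 53 ± 3.19 RPM and the immunoproteasome gene Psmb9 47.2 ± 12 and 33.7 ± 10.1 RPM (adjusted p = 1 for both).

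Loss of H3K9me3 and gain of H3K9Ac met in the same windows in B16, by the presence of islands. This comparison by presence was chosen after the data were seen, while the planned test used edgeR calls. Of the 48512 windows with H3K9me3 in all B16 controls and no H3K9Ac in any, 35 lost the first and gained the second, where independence gave 7.87 (Fisher's exact test, odds ratio 5.15, p = 1.61e-13, windows not being independent). H3K9Ac islands appeared in 2.13% of the windows that lost H3K9me3 and in 0.42% of those that did not. The 35 windows included ones in Zfp382, the DNA repair gene Rad51b, the heme oxygenase gene Hmox2 and the nuclear receptor gene Nr2c2, picked after the windows were seen. In MC38 4 such windows were found where independence gave 0.156. By edgeR calls, 60 of the 58352 windows tested in both marks were lower in H3K9me3 in B16 and 59 higher in H3K9Ac (42 and 22 in MC38). None was both, with 0.0607 and 0.0158 expected, too few for this count to show an excess of the size seen by presence. With 10 kb windows 1 such window was found in MC38 (odds ratio 42.4, Fisher's exact p = 0.0246).

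The lines themselves differed far more than the genotypes. The pigment enzymes Tyr and Dct had 110 ± 9.4 and 80.2 ± 8.09 RPM of H3K9Ac in B16 control and no island in any of the 3 MC38 control libraries (adjusted p = 1.15e-05 and 1.52e-05). Pmel, a melanosome protein, was lower in MC38 at 43.2 ± 6.14 against 65 ± 4.15 RPM (log2 -0.59, SE 0.11, adjusted p = 0.00458), and the epithelial keratin gene Krt8 was higher at 66.5 ± 7.29 against 27.5 ± 7.75 RPM (log2 1.27, SE 0.26, adjusted p = 0.0089). Mlana, with 100 ± 17.3 RPM in B16 and 26 ± 3.16 RPM in MC38, and Sox10, with 95.4 ± 17.8 and 23 ± 20.1 RPM, did not pass (adjusted p = 0.145 and 0.188), nor did Mitf, Cdx2, Vil1, Epcam, Cdh1 and Lgals4 (adjusted p from 0.266 to 0.941). Of 20 melanocyte genes, 13 were lower in MC38 and 15 adjusted over the list alone (camera adjusted p = 1.68e-15, adjusted p = 0.0166 with an estimated correlation), and all 20 lay below 0 under every scaling. With the replicate block the adjusted p values were 8.9e-13 and, with an estimated correlation, 0.0914, so the latter no longer passed. Among 20 gut epithelium genes 2 were higher and 1 lower (camera adjusted p = 0.572). Among 13 fibroblast genes 4 were higher (camera adjusted p = 0.0502, adjusted p = 0.196 with an estimated correlation), and among 13 leukocyte genes 1 was lower.

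In H3K9me3, Mitf, the master regulator of melanocytes, had 46.3 ± 28 RPM in B16 control and no island in any MC38 control library (adjusted p = 0.00842), and Krt8 had islands in all 3 B16 and no MC38 control libraries (adjusted p = 0.0258). Dct had no island in any B16 control library and 40.5 ± 11.6 RPM in MC38 (adjusted p = 0.0846). Olfactory receptors were called higher in MC38 (camera adjusted p = 2.22e-05, adjusted p = 0.615 with an estimated correlation) with 42 members higher and 37 lower, and so were vomeronasal receptors (camera adjusted p = 0.00478, adjusted p = 0.615 with an estimated correlation) with 18 higher and 7 lower. H3K9me3 was higher at 725 and lower at 1107 gene regions in MC38 than in B16 control libraries, and H3K9Ac at 1668 and 2118. The balance turned for H3K9me3 with the replicate block (238 higher and 163 lower) and DESeq2 (3704 and 3546). For H3K9Ac it turned with DESeq2 (3784 and 3655) and over gene bodies (3271 and 3201). The Krt8 H3K9me3 call was lost without any of 5 of the 6 control libraries (adjusted p up to 0.0664). With the replicate block neither the Mitf nor the Krt8 H3K9me3 call was kept (adjusted p = 0.0755 and 0.161), and with stricter islands 0 of these 2 passed.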

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

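The tests of copy number, of scaling within chromosomes, of a common KO effect and of extra copies of chromosomes below were chosen after the data were seen. So were the tests of copy number, weak islands and an effect in both lines for the zinc finger genes, and the counts of called genes by their islands in the other line. The list tests were chosen before. The tests of library depth and of whole-chromosome effects shared by the lines were outside the first plan, and their predictions were written before their own values were seen.

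Zinc finger genes had lower H3K9me3 in B16 KO libraries and the effect was called different from MC38 (camera adjusted p = 0.000848, but adjusted p = 0.917 with an estimated correlation). Fewer copies of their chromosomes would lower H3K9Ac too, yet the median H3K9Ac log2 change of the 84 members with islands in all 6 libraries of both marks was -0.018 (SE 0.03 over genes), which argues against it. The 133 members with islands in all 6 libraries had a median H3K9me3 change of -0.54 (SE 0.06 over genes). This cannot exclude weak islands near the calling limit. A gene region can hold several islands, and a weaker one that is not called in KO libraries lowers the sum. These genes can share reads, so both SEs do not measure the spread between libraries, and the argument against fewer copies rests on the H3K9Ac median. An effect of Setdb1 loss on these genes in both lines is a candidate explanation that stays open, since the list in MC38 reached p = 0.279 with an estimated correlation. The preset camera test called the list in other splits of the B16 libraries as well, at p down to 1.64e-07 against 6.13e-12 for the real split, and in MC38 at p down to 0.00012 against 0.00195, so its p is no measure of how rare the pattern is.

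Mean shares of island reads per chromosome moved alike in both marks between MC38 KO and control libraries. The genotypes' shares overlapped on 18 of 20 chromosomes in H3K9me3 and 19 in H3K9Ac, where chance leaves 10% without overlap. The shifts thus did not separate the genotypes beyond chance. Over the 20 chromosomes the shifts of H3K9me3 and H3K9Ac correlated at r = 0.915 (rho = 0.859, permutation p = 1e-05, the smallest the resamples can give, adjusted p = 0.00011 over 11 relations, r = 0.842 without the 2 chromosomes farthest from the median), and in B16 at r = 0.154 (permutation p = 0.522). Copy number differences between the MC38 cultures may be behind it, since they would move both marks, although within KO replicates 1, 2 and 3 the r was 0.34, 0.741 and 0.338 (rho = 0.284, 0.708 and 0.635, permutation p = 0.224, 0.00073 and 0.0034 for rho). For a single effect common to the 3 KO libraries, the shifts of KO replicate 3 were set beside those of replicates 1 and 2. In H3K9Ac they correlated at r = -0.579 (permutation p = 0.00575, adjusted p = 0.014). The shifts were taken against the mean of all 3 controls, while the H3K9Ac numbers pair the libraries. Deviations shared by a pair push this r below 0, so it cannot decide for H3K9Ac. In H3K9me3, whose numbers did not pair the libraries, this r was -0.595 (adjusted p = 0.014), which argues against a single common effect in that mark. Without the 2 chromosomes farthest from the median r was -0.389 in H3K9Ac and -0.545 in H3K9me3. Setdb1 loss acting on whole chromosomes would need such a common effect. The H3K9me3 values thus argue against it as the whole cause of the MC38 H3K9me3 shifts. For H3K9Ac it stays open, since the correlation of the lines' H3K9Ac shifts, 0.129, is too imprecise to decide.

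B16 KO libraries gained 4721 windows of H3K9me3 and their libraries held more island reads than the controls, so depth is a candidate cause. In windows gained between KO replicates 1 and 3 and control replicates 2 and 3, the held-out KO replicate 2, with fewer island reads than control replicate 1, covered 55.8% against 41.8%, a ratio of 1.33, which lies between the values set for depth alone (1) and against it (1.5). Scaling within each chromosome kept 99.9% of the higher windows, while the number higher was 681 with DESeq2's size factors and 764 with total island reads, against 795. Since 794 of the 795 had no control island, and extra copies would act by lifting a region over the calling limit while a scaling leaves 0 at 0, this does not argue against copy number. Extra copies of the chromosomes with many higher windows would raise H3K9Ac there, and the correlation over chromosomes was 0.0972, too imprecise to decide. A redistribution of H3K9me3 after Setdb1 loss stays open beside depth and copy number, as untested.

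The interaction test of edgeR passed at 1157 H3K9me3 windows and 431 H3K9Ac windows. The genes below were picked for a call in 1 line, and calls came almost only where the other line had islands in all 6 libraries. Of the genes called, 66 of 80 in B16 and 34 of 35 in MC38 passed the interaction in H3K9me3, and 20 of 30 and 21 of 22 in H3K9Ac. The values below thus restate that choice and do not show that the lines differ. In H3K9me3, the adjusted p of the difference was 0.0102 for Dclk1 and Klra4, 0.0151 for Kprp and Il21r, 0.0154 for Adam12 and BC051665, and 0.0156 for Fscb and Reg3a. It was 0.0115 for Ngef and Serpinb1c, 0.0212 for Mblac2 and Clec4g, and 0.0222 for Nol4 and Abca8a. The value was 0.00564 for Litaf, 0.0109 for Oasl1, 0.0116 for Vmn2r56, 0.018 for Lelp1, 0.0182 for Aopep, 0.0367 for Olfr223 and 0.043 for Phactr3. In H3K9Ac it was 0.000114 for H2-T24, 0.000653 for Faap20, 0.00353 for Dnajc18, 0.00719 for Batf2 and Acot1, 0.0135 for Kcnu1, 0.0173 for Syna and Akap7, and 0.0208 for Thegl. Among the lists, clustered protocadherins differed in H3K9me3 (camera adjusted p = 3.16e-08, adjusted p = 0.917 with an estimated correlation), the list being called lower in B16 and not called in MC38. In sequence that no window or gene comparison used, 103 islands lay on the Y chromosome or the mitochondrial genome over all 24 libraries.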

How the results depend on the processing

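The gene body region, TMM within each chromosome and the limma and separation counts over zinc finger genes were chosen after the data were seen, and the other alternatives before. No result that named a covered length changed sides under stricter islands or islands of at least 1 kb. Of the values for single named genes under an alternative, 954 kept the call or, without a call in the main fit, stayed within 1 SE of its log2 change. Direction was not checked for the latter. A call was lost in 138 and gained in 41, and 27 values without a call in the main fit moved by more than that SE. Of the values with a call in the main fit 1 reversed, Kdm5a H3K9Ac in B16, at log2 0.16 over the gene body. The cause was not tested for any change below unless the setting itself leaves fewer libraries or regions. Islands in primer binding sites of retroviral elements, with their alternatives, were not run.

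With DESeq2 in place of edgeR, H3K9me3 calls were 27999 windows and 2253 genes in B16, 15350 and 2010 in MC38, 34266 windows for the difference of the lines' effects and 7250 genes between the control lines. H3K9Ac calls were 9442 and 969, 7547 and 864, 13128 and 7439. With the 6 libraries of a line alone, edgeR called 0 H3K9me3 windows and 0 genes in B16 (11577 and 1950 at an unadjusted p under 0.05), and 27 and 0 in MC38 (200 genes). For H3K9Ac it called 0 and 0 in B16 (5617 and 1168) and 0 and 0 in MC38 (1936 and 528). Limma on regions with islands in all 6 libraries called 0 H3K9me3 windows and 2 genes in B16 (3671 and 1166 unadjusted), and 0 and 0 in MC38 (563 and 52). For H3K9Ac limma called 0 and 0 in B16 (4530 and 1070) and 0 and 0 in MC38 (1474 and 368). These fits had fewer libraries or fewer regions.

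With the replicate block, H3K9me3 calls were 641 windows and 6 genes in B16, 4 and 0 in MC38 (DESeq2 without the block called 15350 and 2010), 537 windows for the difference of the effects and 401 genes between the control lines. The H3K9me3 numbers did not pair these libraries (same-number correlations 0.182, 0.128 and 0.0163 in B16, 0.279, 0.202 and -0.213 in MC38), and not every library correlated best with its own number. For H3K9Ac, which is paired, the block gave 75 windows and 12 genes in MC38 and 268 windows for the difference, and changed no other H3K9Ac count by over 1.5 times. Of the 60 list tests of KO against control, camera with the block called 6 in place of 8, and camera with an estimated correlation 0 (2 at an unadjusted p under 0.05).

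Stricter islands left 192 H3K9me3 windows and 22 genes in B16, 49 and 5 in MC38, 224 windows for the difference and 895 genes between the control lines, and 90 H3K9Ac windows in MC38. DESeq2's size factors gave 89 H3K9me3 windows and 22 genes in MC38 and 705 windows for the difference. In 10 kb windows, calls were 77 for MC38 H3K9me3, 123 for B16 H3K9Ac, 99 for MC38 H3K9Ac and 203 for the H3K9Ac difference, and the odds ratio of the marks' changes in MC38 was 42.4. Over gene bodies, H3K9Ac genes were 42 in MC38 and 6472 between the control lines. Windows with islands in all of 1 genotype and none of the other numbered 2012 in B16 and 187 in MC38 for H3K9me3 and 271 and 166 for H3K9Ac with an overlap of at least 2500 bp, and 4404 for B16 H3K9me3 and 531 for MC38 H3K9Ac with stricter islands.

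Leaving out 1 library at a time gave 870 to 2227 H3K9me3 windows in B16 (2227, 1714, 1635 and 1593 without control 1, KO 2, KO 3 and MC38 KO 3) and 52 to 165 genes. In MC38 it gave 83 to 739 windows and 10 to 154 genes, and leaving out any of the 6 MC38 libraries raised both counts. It gave 1118 to 2310 windows for the difference (2310 without B16 control 1, 2108 without MC38 KO 3) and 1187 to 2497 genes between the control lines (1187 without B16 control 2). In H3K9Ac it gave 237 to 786 windows in B16 (786, 771, 531, 554 and 514 without control 2, 3 and 1 and KO 2 and 3) and 25 to 74 genes, 92 to 635 windows and 14 to 102 genes in MC38, and 384 to 841 windows for the difference. The covered length of H3K9me3 in MC38 differed by -51.4 Mb without KO 1 and 123 Mb without KO 3, and that of H3K9Ac by -14.2 Mb without control 1 and 22 Mb without control 3.

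Simulated changes of 4 on the log2 scale at the H3K9me3 dispersion were not recovered, so a gene without a call is not shown to be unchanged. The simulations varied this spread and not depth, so they do not show what depth limits.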

Other observations

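The counts of pairs of splits for windows shared by both lines or by both marks were chosen after those windows were seen, as were the counts of other splits for windows with islands in all libraries of 1 side and none of the other. The counts of other splits of the edgeR calls and of the lists were planned before.

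H3K9Ac islands were gained in both lines in 12 windows where independence among 17619 eligible windows gave 4.64 (Fisher's exact p = 0.0025). Of 400 pairs of splits 14 gave as many, the highest other 90, and 38 gave as large a ratio to the number expected over all windows. The 12 included a window in Foxo1, a transcription factor gene of insulin signalling, picked after the windows were seen. By limma on genes with islands in all 6 B16 libraries, H3K9me3 fell at Cgnl1, a cell junction gene, from 144 ± 8.76 to 20.9 ± 3.61 RPM (log2 -2.77) and at Stag1, a cohesin subunit gene, from 91.6 ± 14 to 14.8 ± 0.624 RPM (log2 -2.58, limma adjusted p = 0.046 for both), and no other gene passed. Several zinc finger genes outside the rule for named genes had large steps in B16 H3K9me3, with Zfp934 at 211 ± 32.5 and 76.8 ± 11.5 RPM, Zfp949 at 71.4 ± 6.29 and 24.5 ± 2.16 RPM and Zfp420 at 79.1 ± 18 and 28.1 ± 2.76 RPM in control and KO libraries, none of which passed over all genes by edgeR or limma. Zinc finger genes with an H3K9me3 island in all 3 libraries numbered 182 in B16 control, 147 in B16 KO, 150 in MC38 control and 125 in MC38 KO libraries, of 416 in the list. Protein-coding genes with such islands numbered 4869, 4540, 3190 and 2347 of 21900.

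In B16, chromosome 10 held 3.32 ± 0.138% of H3K9me3 island reads in control and 2.60 ± 0.249% in KO libraries, and chromosome 16 held 2.61 ± 0.0914% and 2.08 ± 0.245%. Of the 20 chromosomes, 4 had all KO libraries below all control libraries in B16 H3K9me3 (3, 10, 15 and 16) and 2 had all above (1 and 8), where chance gives 10% of chromosomes in either direction. The X chromosome's share of H3K9Ac island reads was lowest in replicate 3 in each of the 4 groups, at 0.573%, 0.539%, 0.429% and 0.416% against 0.647% to 0.764% in the other libraries.

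A change from methylation to acetylation in the same windows after Setdb1 loss is a hypothesis that the 35 B16 windows with H3K9me3 lost and H3K9Ac gained may bear on. Of 400 pairs of splits of the H3K9me3 and H3K9Ac libraries, 2 gave as many such windows, the real pair included, with 42 in the highest other. The raw number is thus rare among regroupings but was tested on the windows it was found in. Of the 20 pairs that use the same split in both marks, 1 gave as many, the real one, and the highest other gave 13. A raw number also grows with the windows lost and gained in a split, 2726 from H3K9me3 and 1323 in H3K9Ac in the real one. No ratio to the number expected was compared over these pairs, so the ranks do not show a rare overlap beyond what those numbers give. In MC38 19 of 400 pairs gave at least the 4 windows found, with 37 in the highest other. For the 22 windows that lost H3K9me3 in both lines, 21 of 400 pairs of splits gave as many, the highest other 139, so chance is not excluded by the count, and 17 gave as large a ratio to the number expected over all windows.

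Other splits of the same libraries were set beside each count, the real split included. For 3 against 3 libraries, 10 splits cannot give a share under 0.05. H3K9me3 windows in B16 gave as many calls in 1 of 10 splits (1039 real, highest other 511) and genes in 1 (80 and 8). In MC38 H3K9me3, 7 of 10 splits gave as many windows (148 real, highest other 980) and 5 as many genes (35 and 176). For H3K9Ac, 3 of 10 splits gave as many windows in B16 (322 and 502) and 4 as many genes (30 and 69), and in MC38 7 gave as many windows (161 and 889) and 7 as many genes (22 and 100). The control libraries of the lines gave 1832 H3K9me3 genes against 0 in the highest other split, and 3786 H3K9Ac genes against 3, with 1 of 10 splits as large for each. For windows with islands in all libraries of 1 side and none of the other, 1 of 10 splits gave as many in B16 H3K9me3 (7447 and 3613), 9 in MC38 H3K9me3 (1033 and 11052), 3 in B16 H3K9Ac (1501 and 2678) and 7 in MC38 H3K9Ac (804 and 3630). As many lists were called in 4 of 10 splits for B16 H3K9me3 (4 real, highest other 5), 5 for MC38 H3K9me3 (3 and 4), 5 for B16 H3K9Ac (1 and 3) and 10 for MC38 H3K9Ac (0 and 5). Of 25 splits for the difference of the KO effects, 4 gave as many H3K9me3 windows (1157 and 2160) and 12 as many H3K9Ac windows (431 and 1038), so chance is not excluded for either count over these splits.

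Splits that call several times the real count point to a structure of the MC38 libraries other than genotype. The split with 11052 such H3K9me3 windows set MC38 control replicates 1 and 3 and KO replicate 1 against the other 3 libraries. In H3K9Ac, where the replicate numbers pair the libraries, splits that part all 3 pairs are the ones to compare with the real split. These 3 other splits gave 37, 14 and 23 windows in B16 (322 real) and 0, 0 and 1 genes (30 real), and in MC38 225, 21 and 84 windows (161 real) and 25, 1 and 3 genes (22 real). For the difference of the KO effects, 5 other splits parted all 6 pairs and gave 77 to 195 H3K9Ac windows (431 real), too few splits for a share under 0.05. Splits with more H3K9Ac calls than the real one put libraries of 1 number on the same side, apart from the MC38 split with 225 windows and 25 genes.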
